A study of Mus musculus with 2 samples.

How the data were processed

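Suz12, a core subunit of Polycomb Repressive Complex 2 (PRC2), the enzyme that methylates histone H3 on lysine 27, was mapped by chromatin immunoprecipitation followed by sequencing in mouse embryonic stem cells. Per the labels, 2 libraries made with the same rabbit antibody against Suz12 belong to the series. The wild-type library comes from E14 cells, a widely used mouse embryonic stem cell line, kept for 72 h in serum medium with 1 µM all-trans-retinoic acid and without leukemia inhibitory factor, the cytokine that holds these cells undifferentiated. The other library comes from Suz12 knockout cells at 0 h. A peak list was used for the wild-type library only, and the knockout library was not analysed here. The groups differ in genotype and in time together and each has 1 library, so no comparison between groups was made, no replicate error could be given and no p-value is reported.

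Per the submitters' processing notes, the authors used Bowtie, MACS and the mouse build GRCm38 (mm10). Versions, parameters, the control library and any pooling of libraries are not given in the sources used here. The deposited list gives for each peak its start, its end and a score, and the scale of this score is not stated in the file. By the convention of MACS for lists of this layout the score is a scaled negative logarithm of the peak's p-value. The deposited scores pile up at 3100, a value shared by 325 peaks, and 30 further peaks score above it, so ranks near the top carry little information. A score above 3100 should not be read as a stronger peak than a score of 3100. The scores are the authors' own values and were used only to rank, describe and filter peaks. The list does not give reads, so the sequencing depth is unknown and a gene without a peak may hold signal below the authors' threshold.

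Peaks were placed on the 21631 protein-coding genes that a RefSeq table of the same build gives for the 20 chromosomes with peaks. This table gives the outer ends of each gene but no strand, exons or transcripts. The planned promoter rule was therefore replaced by the rule that a gene has a peak when a peak lies within 2.5 kb of either of its ends, so the far end of a gene counts as well as its start. Exons, introns and untranslated regions could not be told apart, and peaks were classed by their midpoint as at a gene end, inside a gene or outside genes. Planned results on CpG islands, CpG content and repeats were not run because the genome sequence was not used here.

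As a background, the same peak widths were placed at random 100 times on the same chromosomes, between the outermost genes or peaks of each. Assembly gaps could not be left out of this stretch. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat genes or peaks as independent, although neighbours are not. Peaks within 3 kb of each other were joined into domains. The relation between score and width was described with Spearman's rho and Pearson's r across peaks, which are not independent replicates.

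The 23 gene lists were written before the data were examined, as were the rule for naming genes and the stricter or looser settings named last, apart from those said to be added. They cover the Hox clusters, other homeobox transcription factors, neural lineage regulators, mesoderm and heart regulators, endoderm regulators, Wnt ligands, receptors and antagonists, and BMP, TGF-beta, hedgehog, FGF and Notch signalling, which together form 7 developmental lists. The others cover pluripotency genes, the retinoic acid pathway and its targets, cell cycle inhibitors and tumour suppressors, Polycomb subunits, ion channels and neurotransmitter receptors, neuronal structural genes, cardiac and skeletal muscle structural genes, trophoblast genes, germline genes, ribosomal protein genes, housekeeping genes, immune and blood cell genes, liver and gut differentiation genes, fibroblast and feeder cell genes, primitive and parietal endoderm genes, and imprinted genes. Of the 924 symbols written, 7 belong to non-coding genes and were left out, 4 matched by an older name and 0 were unmatched, and the lists hold 873 distinct genes. Some genes sit on more than 1 list. Each list's count was set beside 10000 random lists of the same size drawn from all protein-coding genes, since matching on CpG islands was not possible. A list was called above or below the background when at most 21 of the 10000 random lists had as many or as few members with a peak, a level of 5% in each direction shared over the 23 lists. A limit shared over both directions, added after seeing the data, would be 10 random lists. These counts describe this library and are not p-values across genes.

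Named genes are the 25 with the highest-scoring peaks, up to 4 top-scoring members of each list and up to 4 members without a peak in alphabetical order, the genes in the 10 longest domains, and the genes nearest to the 5 highest-scoring peaks away from gene ends. Any member of the pluripotency, Polycomb and retinoic acid lists could be named as well. Any other gene named was chosen after its values were seen. Some genes that this rule names are not reported here.

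The alternatives were stricter score limits, other distances to the gene end (a peak covering it, 1 kb and 5 kb), genes of any kind, other joining distances and classing by any overlap. Added after seeing the data were genes with a curated transcript, peaks anywhere in or near a gene, random lists matched on gene length and on neighbouring gene ends within 250 kb, the count of genes with a peak under these rules, and chromosome X left out. The procedure was run on simulated peaks over the 21631 genes, where 200 of 200 genes given a peak at an end were recovered. This recovery follows from how the peaks were planted, so it checks the code and not the rule. A 5% level was passed by 3.5% of 200 random gene lists. Because these lists were random, they cannot show the error for lists of neighbouring genes that share peaks, such as the Hox clusters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.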

Results

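The series asks, by its title, how gene silencing relates to the recruitment of PRC2 to CpG islands. The data are 3373 Suz12 peaks from 1 library of wild-type E14 cells after 72 h of differentiation with retinoic acid. The peaks lay on chromosomes 1 to 19 and X and covered 8.05 Mb, which is 0.308% of the stretch searched. Their width ran from 318 to 20581 bp with a median of 1849 bp, and their score from 150.3 to 3233 with a median of 572.

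Suz12 peaks gathered at the ends of genes for transcription factors, signalling molecules, ion channels and neurotransmitter receptors. The highest deposited score, 3233, belonged to a peak at Foxc1, a forkhead factor of mesoderm, on GRCm38 chromosome 13 from 31805547 to 31809536. The top scores need not mark the strongest peaks, since 325 peaks share the value 3100, among them the widest, of 20581 bp. Peaks of score 3230 lay at Prdm8, a zinc-finger factor of neurons, and at Mdga1, a neuronal cell-surface protein. Members of the homeobox list took 6 of the 25 top places, namely Msx1 (3187), Pdx1 of the pancreas (3180), Irx5 (3173), Nkx2-5 of the heart (3171), Dlx4 (3156) and Dlx6 (3141). Gata6, a factor of endoderm and heart, had a peak of 8319 bp with score 3182, and Grhl2, an epithelial factor, a peak with score 3190. Other regulators among the top 25 were Bhlhe41 (3168) and Nr3c2, the mineralocorticoid receptor (3160), together with the ligand gene Wnt10b (3165).

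Genes for membrane and extracellular proteins were also among the top 25. Nell1, a secreted protein, had a score of 3220 and Grid1, a glutamate receptor subunit, a score of 3200. The potassium channel genes Kcnk13 and Kcng3 had scores of 3157 and 3106. Lox, which crosslinks collagen, scored 3140, Lingo1 3135 and Nxph1 3110. Efcc1, which is not placed in this group here, scored 3164. A single peak on chromosome 7 from 139943386 to 139946174, with score 3155, covered the pluripotency gene Utf1 and lay beyond an end of its neighbour Kndc1.

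Of the 3373 peaks, 2510 (74.4%, 95% interval 72.9 to 75.9) lay within 2.5 kb of an end of a protein-coding gene. Random placement gave 10.3% ± 0.507 (SD over 100 placements) and at most 11.5%. By midpoint, 69.1% of peaks were at a gene end, 19.2% inside a gene and 11.6% outside genes, against 7.38%, 36.8% and 55.8% at random. Counted by gene, 2540 of 21631 protein-coding genes (11.7%, 11.3 to 12.2) had a peak, against a mean of 402 and a maximum of 462 in the random placements. Of 1386 genes longer than 20 kb with a peak at an end, 1343 (96.9%) had it at 1 end only. At 229 of the 2540 genes (9.02%) the best peak lay wholly beyond the gene; among the genes named these include Dlx6, Cdkn2c and Hoxd12, where the best peak over the gene itself scored 2837, 439 and 2886.

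The question of which kinds of genes held Suz12 was put to the 23 gene lists. The 7 developmental lists hold 368 distinct genes, of which 283 (76.9%) had a peak, against 2138 of 20758 genes (10.3%) outside all lists. Their peaks also scored higher, since 148 of the 283 (52.3%, 46.3 to 58.2) had a best score of 3100 or more, against 204 of the 2257 other genes with a peak (9.04%, 7.89 to 10.3). Their median best peak was 4377 bp wide, against 1879 bp for the others.

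Homeobox factors outside the Hox clusters led the lists, with a peak at 85 of 90 genes (94.4%, 87.5 to 98.2). Msx1, Pdx1, Irx5 and Nkx2-5 had the highest scores, and 62 of the 85 reached 3100. The members without a peak included Lhx4, Meox1, Meis1 and Meis2, and Lhx4 had a peak inside the gene. Neural lineage regulators had a peak at 56 of 60 genes (93.3%, 83.8 to 98.2), with the widest at Nr2e1 (16364 bp), Pax7 (15601 bp), Zic2 (15289 bp) and Ebf3 (15091 bp), all with score 3100. The 4 neural genes without a peak at an end were Lmo3, Neurod4, Sox11 and Nr2f1, the last of which had a peak inside the gene. None of 10000 random lists of the same size had as many genes with a peak as either list.

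Mesoderm and heart regulators had a peak at 39 of 50 genes (78.0%, 64.0 to 88.5), led by Foxc1, Gata6, Tbx1 (12020 bp) and Osr2 (10782 bp). Bmp4, a ligand that patterns mesoderm, and the muscle factor Myf5 had none. The list of endoderm regulators had a peak at 16 of 23 genes (69.6%, 47.1 to 86.8), among them Pdx1, Otx2, Nkx2-1 and Prox1, while Afp, Cer1, Elf3 and Gata1 had none. It was kept as written and also holds genes that are not endoderm regulators, such as Afp and Gata1. Of its 23 genes, 11 sit on another list as well. Wnt ligands, receptors and antagonists had a peak at 27 of 48 genes (56.3%, 41.2 to 70.5), with Wnt10b, Wnt7b, Wnt1 and Wnt3a at the top. Axin2, a target of Wnt signalling, and the antagonist genes Dkk1, Dkk3 and Dkk4 had none. The BMP, TGF-beta, hedgehog, FGF and Notch list had a peak at 40 of 64 genes (62.5%, 49.5 to 74.3), led by the Notch ligand gene Dll4, Gdf7 and the hedgehog genes Dhh and Ihh, and lacked peaks at Bmp4, Bmp5 and Fgf10. No random list had as many for any of these 4 lists.

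Genes for ion channels, neurotransmitter receptors and neuronal structure were marked as well. The list of channels and receptors was not limited to genes of neurons. Ion channels and neurotransmitter receptors had a peak at 49 of 71 genes (69.0%, 56.9 to 79.5), with Grik3, Kcnk9, Grin1 and the adrenergic receptor gene Adra2a at score 3100. The peak counted for Grin1 overlapped an end of that gene and covered all of its neighbour Lrrc26, named after its values were seen. The median score of the channel and receptor list was 799.98, against 3100 for the homeobox and neural lists. Cacna1a, Cacna1e and Chrna4 had a peak inside the gene only. Neuronal structural genes had a peak at 20 of 37 (54.1%, 36.9 to 70.5), including Gad1 and Gad2, which make the transmitter GABA, its vesicle transporter gene Slc32a1, and Chat, which makes acetylcholine. Calb1, Calb2, Dcx and Dlg2 had none. Again no random list had as many for either.

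**Figure D1:**
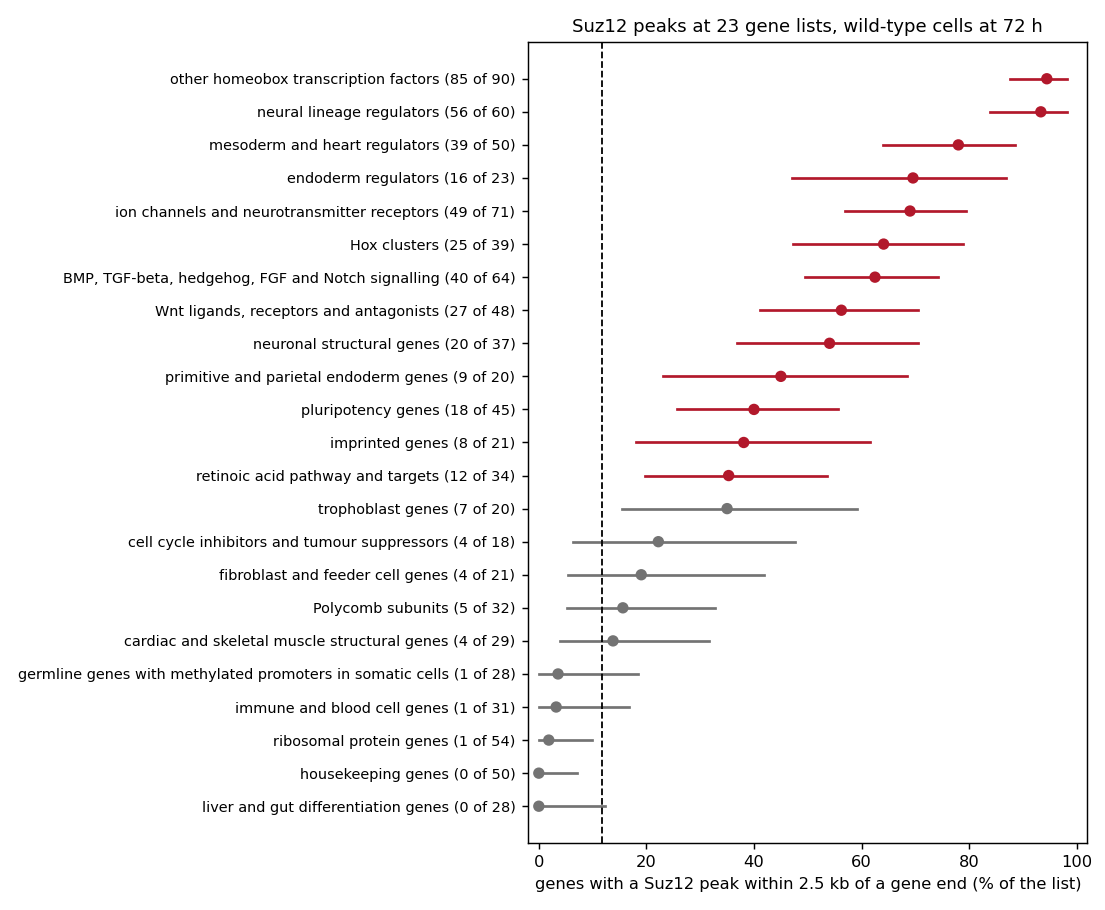
Percentage of the genes of each of 23 lists with a Suz12 peak within 2.5 kb of a gene end (points), with exact 95% binomial intervals (lines); the dashed line is the 11.7% of all protein-coding genes. Red marks the 13 lists called above the background and grey the 10 called neither way; homeobox factors stand highest at 94.4% and no housekeeping gene has a peak.

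Pluripotency genes had a peak at 18 of 45 (40%, 25.7 to 55.7), and no random list had as many. The highest scores were at Utf1 (3155), the germ cell and pluripotency factor Prdm14, Fgf4 and Klf2 (3100 each), followed by Gbx2 (2264), Prdm1 (2063), Klf4 (1160) and Sox2 (993). Lower-scoring peaks lay at Tcea3 (955), Jam2 (786), Socs3 (586), Klf5 (449), Tdgf1 (341), Nr0b1 (336), Icam1 (332), Tbx3 (319) and Mycn (174). Pou5f1 and Nanog, central factors of pluripotency, had no peak, nor did Zfp42, Tfcp2l1, Dppa2, Dppa3, Dppa4, Dppa5a, Lin28a, Sall4 or Stat3. Esrrb and Nr5a2 had a peak inside the gene but at neither end. Of the 45 genes, 7 are also on other lists.

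Among genes of the retinoic acid pathway and its targets, 12 of 34 (35.3%, 19.7 to 53.5) had a peak, and 9 of the 34 are also on other lists. The genes with a peak included Fgf8 (3100), Sp8 (3031), Aldh1a2 (2724), Crabp1 (2376), Gbx2 (2264), Cdx1 (1662), Aldh1a3 (851), Rbp4 (417), Cyp26a1 (411), Rxrg (202) and Rarg (174). Aldh1a2 and Aldh1a3 make retinoic acid and Cyp26a1 degrades it. The receptor genes Rara, Rarb, Rxra and Rxrb had no peak, nor did Crabp2, Stra6, Stra8, Dhrs3, Rdh10 or Hoxb1, and Cyp26b1 had a peak inside the gene only. As many genes were reached by 3 of 10000 random lists, but by 32 when random lists were matched on gene length and neighbouring gene ends, which ends the call.

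Of the Polycomb subunit genes, 5 of 32 (15.6%, 5.28 to 32.8) had a peak, a count that 3204 random lists reached. They included Cbx8 and Bmi1, both members of Polycomb Repressive Complex 1, and Phf19 (1037) and Pcgf5 (577). The best peak of Cbx8 (10037 bp) and that of Bmi1 (3528 bp), each with score 3100, lay beyond an end of the gene, and the best peak over the gene itself scored 3100 at Cbx8 and 1853 at Bmi1. Suz12 itself, Ezh2, Eed, Jarid2 and Mtf2 of PRC2 had no peak, and neither did Ring1, Rnf2 or Cbx7. Cbx2 had none within 2.5 kb, but it lay close to a wide domain at Cbx8. The gene ended at 119031275 on chromosome 11 and the domain began at 119034006. Kdm2b, a CpG-binding subunit, had a peak inside the gene only.

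Primitive and parietal endoderm genes had a peak at 9 of 20 (45.0%, 23.1 to 68.5; 5 random lists had as many), led by Gata6, Pdgfra, Ihh and Amn, and lacked one at the collagen genes Col4a1 and Col4a2. Of these 20 genes, 8 are also on other lists, among them Gata4, Gata6, Sox7, Sox17, Pdgfra and Ihh, which all had a peak. Among the genes on this list alone, only Amn, Foxq1 and Thbd had a peak, so the call leans on the shared genes. Imprinted genes had a peak at 8 of 21 (38.1%, 18.1 to 61.6; 20 random lists), including Grb10, Rasgrf1, Cdkn1c and Slc22a18, and not Igf2r, Impact, Magel2 or Mest. The peak counted for Slc22a18 lay beyond its end and covered its neighbour Phlda2, named after its values were seen, so the 8 genes rest on 7 peaks. The call on imprinted genes was lost with a limit of 10 random lists, shared over both directions, and at every other distance to the gene end, with 920 random lists when the peak had to cover it. Trophoblast genes had a peak at 7 of 20 (35.0%, 15.4 to 59.2; 60 random lists), led by Hand1, Tfap2c, Eomes and Cdx2. This list was not called, but passed with peaks at or above the median score, where 4 random lists had as many. Cell cycle inhibitors and tumour suppressors had a peak at 4 of 18 (22.2%, 6.41 to 47.6; 1479 random lists), namely Trp73, Cdkn2c, Cdkn1c and Cdkn2a. Fibroblast and feeder cell genes had 4 of 21 (19.05%, 5.45 to 41.9; 2340 random lists), namely Pdgfra, Twist2, Thy1 and Fbn1, with none at Col1a1, Col1a2 or Col3a1. Muscle structural genes had 4 of 29 (13.8%, 3.89 to 31.7; 4502 random lists), namely Acta1 (989), Ryr2 (713), Ckm (205) and Des (198).

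Housekeeping, ribosomal protein, liver and gut, immune and blood cell, and germline genes had few peaks or none. No peak lay at any of 50 housekeeping genes (interval up to 7.11%), such as Actb and B2m, and 26 random lists had as few. Liver and gut genes had 0 of 28 (up to 12.3%; 319 random lists as low), with none at Alb, Apoa1, Apoa2 or Apob. Ribosomal protein genes had 1 of 54 (1.85%, 0.0469 to 9.89; 85 random lists as low), with none at Rpl10a, Rpl11, Rpl12 or Rpl13. Immune and blood cell genes had 1 of 31 (3.23%, 0.0816 to 16.7; 1082 random lists as low), a peak of score 159 at Cd14. Germline genes had 1 of 28 (3.57%, 0.0904 to 18.3; 1476 random lists as low), at Dmrt1, where the best of 3 peaks (3100) lay beyond an end and the best over the gene scored 2061. None of these 5 lists was called. Housekeeping genes passed within 5 kb (11 random lists) and ribosomal protein genes within 1 kb (19 random lists), but neither with the limit of 10 shared over both directions.

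Of the 10 longest Suz12 domains, 4 lay over Hox genes. Joining peaks within 3 kb gave 2990 domains, 105 of them longer than 10 kb. The longest, 50755 bp on chromosome 2 from 74654543 to 74705297, ran from Evx2 through Hoxd13, Hoxd12, Hoxd11, Hoxd10 and Hoxd9 to Hoxd8. The next was 43256 bp on chromosome 6 from 52211548 to 52254803, over Hoxa7, Hoxa9, Hoxa10, Hoxa11 and an end of Hoxa3. On chromosome 15, 35624 bp from 102947070 to 102982693 held Hoxc9, Hoxc10 and Hoxc11, and 23166 bp from 102920862 to 102944027 held Hoxc12 and Hoxc13. A domain of 25722 bp on chromosome 11, from 119034006 to 119059727, held the Polycomb gene Cbx8. The others covered Uncx (23906 bp), Zic5 and Zic2 with an end of Pcca (23795 bp), Pax2 (23529 bp), Neurod2 with Gm33099 (20935 bp), and Dlx1 with Dlx2 (20219 bp).

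Within the Hox clusters, which pattern the body axis, Suz12 followed the numbering of the genes. The list as a whole had a peak at 25 of 39 genes (64.1%, 47.2 to 78.8), and no random list had as many. Genes of paralogue groups 9 to 13 all had a peak (16 of 16, 79.4 to 100%) and peaks covered on average 90.9% of each gene. Groups 6 to 8 had a peak at 5 of 8 genes (24.5 to 91.5%) with 20.6% covered, and groups 1 to 5 at 4 of 15 genes (7.79 to 55.1%) with 4.81% covered. The gene annotated as Hoxa3 spans its neighbours Hoxa4, Hoxa5 and Hoxa6, and its peak lay at the end next to Hoxa7; Hoxb3 and Hoxd3 likewise span a neighbour. Without these 3 genes, 2 of 12 genes of groups 1 to 5 had a peak, namely Hoxd1 (351) and Hoxd4 (184), named after their values were seen.

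The 4 clusters differed in extent. At Hoxa, on chromosome 6, peaks covered 40.02% of the cluster, beginning at 52211548, and Hoxa2, Hoxa4 and Hoxa5 had none. At Hoxc, chromosome 15 from 102921131 to 103036856, they covered 50.6%, with the widest peak of the list, 20581 bp, over Hoxc11 and part of Hoxc10. At Hoxd, chromosome 2 from 74668225 to 74765142, they covered 43.6% and all 9 genes had a peak. At Hoxb, chromosome 11 from 96194316 to 96368254, they covered 8.04% and 3 of 10 genes had a peak. These were Hoxb6 (374), Hoxb9 (643) and Hoxb13 (680), named after their values were seen, against a best score of 3100 near each gene of groups 9 to 13 in the other clusters. Spearman's rho between group number and covered percentage across the genes of a cluster was 0.79 at Hoxa, 0.69 at Hoxb, 0.89 at Hoxc and 0.76 at Hoxd; neighbouring genes share peaks and are not independent.

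**Figure D2:**
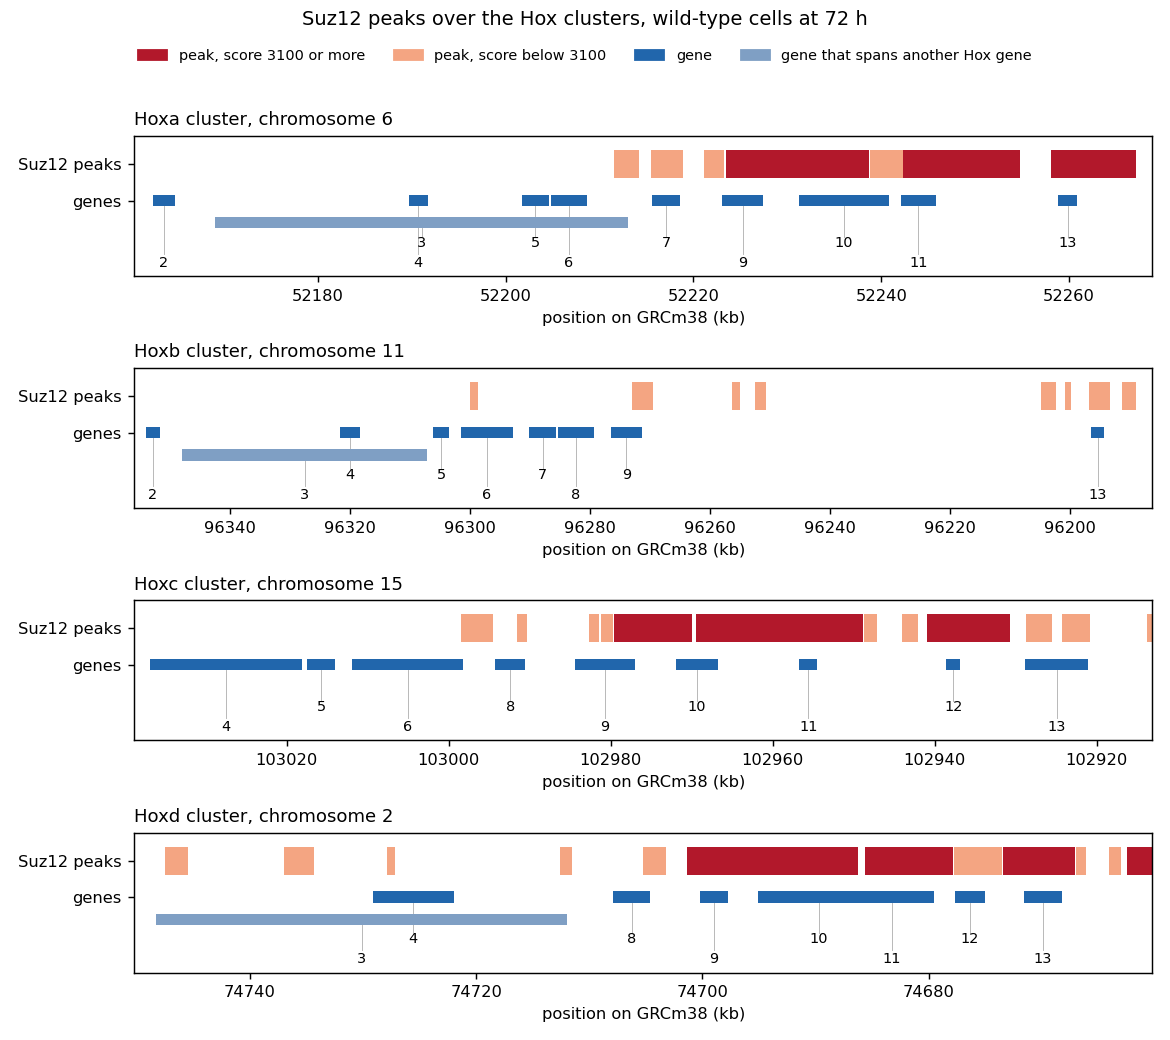
Map of the 4 Hox clusters on GRCm38 (position in kb), each drawn from group 2 or the next group present, with low group numbers at the left and genes of group 1 left out, with Suz12 peaks as boxes above (dark red for a score of 3100 or more, light red below) and genes in blue labelled by group number, pale where a gene spans another Hox gene. Groups 9 to 13 lie under peaks that cover on average 90.9% of each gene, and the Hoxb cluster is the least covered at 8.04%.

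Some of the highest-scoring peaks lay away from the ends of protein-coding genes. The highest of these, 7864 bp on chromosome 7 from 79495755 to 79503618 with score 3226, lay at the microRNA host gene Mir9-3hg, 27844 bp from Polg, the nearest protein-coding gene. A peak on chromosome 18 from 78046529 to 78049429 (score 3198) lay inside Siglec15. Another on chromosome 8 from 84770865 to 84776967 (3179) lay inside Nfix, a nuclear factor of brain and muscle, and another on chromosome 10 from 127078754 to 127082610 (3159) inside Agap2. A peak on chromosome 12 from 56519167 to 56522067 (3148) lay 9868 bp from Nkx2-1, a factor of lung, thyroid and forebrain.

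Wide peaks scored higher than narrow ones. Across the 3373 peaks Spearman's rho between score and width was 0.89 and Pearson's r of their logarithms 0.87. Peaks wider than 5 kb numbered 223 and held 21.8% of the covered length, and 355 peaks (10.5%) scored 3100 or more.

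**Figure D3:**
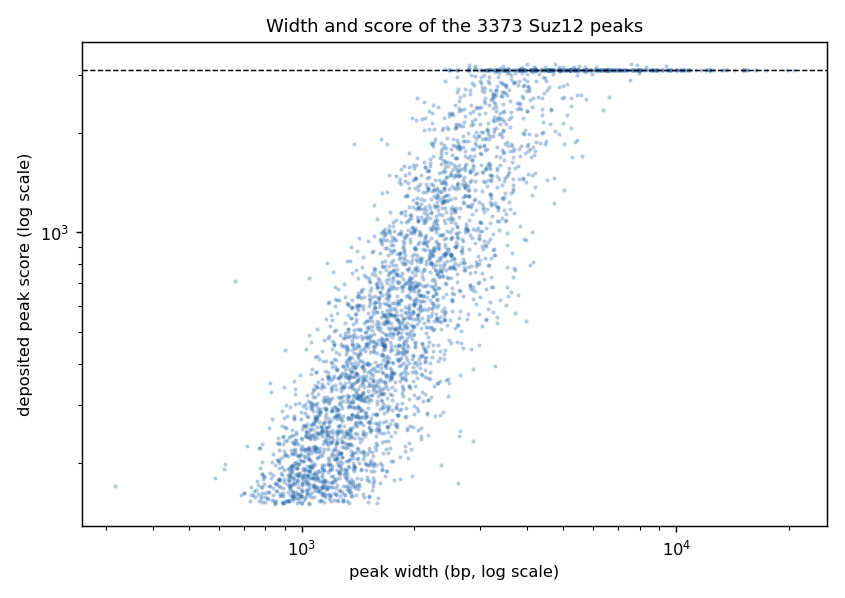
Deposited score against width in bp, both on log axes, for the 3373 Suz12 peaks (1 point each); the dashed line marks a score of 3100, where 325 peaks lie. Score rises with width (Spearman's rho 0.89), and 30 peaks lie above the line.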

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

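Of 168 alternative values, 141 stayed within the interval or within 1.5 times the main count, 27 moved and 0 reversed. For small gene lists the interval is wide, so this tally says little about how stable their shares are. Imprinted genes, at 38.1% in the main result and 19.05% with covering peaks, counted as unmoved although their call was lost. The number of peaks fell to 1687 at or above the median score, with 1397 genes and 1540 domains, by construction. The share of peaks at gene ends was 76.6% with scores of at least double the lowest and 78.7% at or above the median; it was 52.3% when the peak had to cover the end, 66.9% within 1 kb, 80.3% within 5 kb and 82.2% for genes of any kind. Classed by any overlap, 74.4% of peaks were at a gene end, 15.2% inside and 10.4% outside genes. Ribosomal protein genes fell to 0% under both score limits, with covering peaks and within 1 kb, and immune genes to 0% under both score limits and with covering peaks, each through the loss of 1 gene. Mesoderm and heart regulators were at 58% with scores at or above the median and at 64% with covering peaks. Ion channels and receptors were at 52.1% under each of these and at 81.7% with peaks anywhere in or near the gene, an alternative chosen after seeing the data. Domains longer than 10 kb numbered 64 when joined within 1 kb and 195 within 10 kb. Among peaks scored below 3100, rho between score and width was 0.852. Where not given by construction, the cause of these shifts was not tested. Calls on lists changed for trophoblast, ribosomal protein, housekeeping, imprinted and retinoic acid genes only, among 23 lists and 7 alternatives. With the limit shared over both directions 12 of the 13 calls passed, all but imprinted genes. Alternatives on CpG islands and repeats were not run because the genome sequence was not used here. No paired analysis was possible because only 1 library has a peak list here, and for the same reason no library could be left out. The depth is unknown, so the absence of a peak does not bound the signal.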

Other observations

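The tests on Hox genes and the counts of microRNA genes, gene families and genes per chromosome were chosen only after their results or the data were seen; the tests on chromosome X and on peaks away from gene ends were written down before their results were seen. The genes named here were chosen after their values were seen.

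Of 1228 annotated microRNA genes, 58 (4.72%, 95% interval 3.61 to 6.06) had a peak in or within 2.5 kb of them, against a mean of 12.4 and a maximum of 32 in 100 random placements. At 26 of these the peak was not at an end of a protein-coding gene. Some entries overlap each other and share a peak, such as Gm51285 with Mir9-3 and Mir129b with Mir129-2. The 58 entries thus rest on fewer distinct peaks, while the interval treats them as independent. Peaks with a score of 3100 or more lay at Mir9-3, Mir9-1, Mir124a-1 and Mir124a-3, microRNAs abundant in neurons or their precursors, and at the sensory microRNAs Mir183 and Mir96. Mir124a-2 had a peak with score 678 and Mir9-2 a peak with score 232. Mir196b and Mir196a-2 lay in or near the wide peaks of the Hoxa and Hoxc clusters.

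Grouped by the stem of the gene symbol, 153 families had at least 15 genes, and 8 of them had as many genes with a peak in fewer than 1 of 1000 random lists. They were Wnt (16 of 19), Sox (13 of 19), Syt (10 of 17), Fgf (12 of 22), Pde (11 of 26), Pou (8 of 16), Galnt (8 of 17) and Adamts (8 of 19). Syt genes encode synaptotagmins, Pde genes phosphodiesterases, Galnt genes enzymes of O-glycosylation and Adamts genes extracellular proteases, none of which the lists were built around, although Syt1 is on the neuronal structural list. The random lists used for families were not matched on gene length or neighbouring gene ends, so an effect of these on the family counts was not tested. At the other end, peaks were rare at olfactory receptors (Olfr, 2 of 1110), vomeronasal receptors (Vmn, 0 of 355), zinc-finger genes of the Zfp stem (22 of 397) and keratin-associated proteins (Krtap, 0 of 56).

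Chromosome X held 53 peaks (0.311 per Mb, against 1.36 on the autosomes), and 41 of its 966 genes (4.24%, 3.06 to 5.71) had a peak, against 12.1% on the autosomes. A lack of developmental list genes was tested with autosomal rates within and outside those lists. These rates give 108 genes, above the exact 95% Poisson interval of the 41 observed (29.4 to 55.6). The lists hold only 1.76% of autosomal genes, so the test could hardly have come out otherwise, and no conclusion is drawn from it. The gap was present among genes outside the lists, where 3.95% on X had a peak against 10.9% on the autosomes. Lower signal from a single X, as male cells carry, cannot be told apart from the rest: the median score of X peaks, 428 against 575, stood at percentile 6.31 of 10000 random sets of as many autosomal peaks, between the limits set for either answer. No biological explanation was tested.

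Low-numbered Hox genes mostly lacked peaks. Gene ends annotated away from the true start cannot be told apart from other sources: 0 of the 14 Hox genes without a peak at an end had a peak elsewhere in or near the gene, but 11 of them are shorter than 5 kb, so the windows at both ends already span them. Loss of Suz12 on retinoic acid, which is known to switch on low-numbered Hox genes, may be the source of this pattern, but an untreated wild-type peak list was not analysed here. The 35.3% of retinoic acid genes with a peak cannot separate loss from absence before treatment, so this stays an untested hypothesis.

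The 863 peaks away from protein-coding gene ends had a median score of 453, against 623 at gene ends. Ends of long non-coding genes could account for part of them, since 24.2% (21.4 to 27.2) lay within 2.5 kb of such an end against at most 7.76% in 100 random placements. Starts inside protein-coding genes could account for others, since 59.3% (56.0 to 62.6) had their midpoint inside such a gene against at most 43.6% at random, although the annotation used gives no internal starts. Weak or background calls remain open, because the median of 453.4 lies between double the lowest score (300.6) and the median of all peaks (572). No biological explanation was tested.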
